A study of Mus musculus with 9 samples.

How the data were processed

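The 9 libraries came from mouse ESC and from MN made from them, and each was a 4C-seq library from 1 of 3 bait positions. Per the labels' protocols, ESC were grown with 1 μM PD0325901 (a MEK inhibitor) and 3 μM CHIR99021 (a GSK3 inhibitor), and differentiation used 1 μM retinoic acid and 0.5 μM smoothened agonist. Chromatin was fixed in 2% formaldehyde for 10 min, cut with DpnII and then with Csp6I, and 1 μg of template was amplified by inverse PCR with barcoded adapters, per the labels' protocols. Groups, cell types, genotypes and bait coordinates were taken from the labels. A ligation product can only be seen where both enzymes leave a usable fragment, and PCR without molecular identifiers does not count molecules, so heights depend on fragments and on amplification as well as on contact.

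The deposited values are a contact signal, given as running medians with the 20th and 80th percentiles over windows of growing size on a 1 kb grid, per the file headers for the first windows. The genome build is mm9, per the submitters' processing notes. The aligner, the fragment filters and the scaling steps are not given in the sources used here. Each table held 176 positions from 52074984 to 52249984 and 145 columns, of which the header named 5. The values put the remaining columns into 48 window sizes, each with a median and both percentiles. The largest 6 kb median was 1 in every library, so the deposited signal is relative to each library's own maximum and is not an amount. In every library 26 positions were at 0, the same ones throughout, and 2 had no value. Each library's most common nonzero value, after rounding to 4 decimals, was from 0.0012 to 0.0098 of signal, and 64 to 107 positions lay above 1.5 times it. Lower nonzero values also occur, so it is not a lowest level. No counts are given, so the depth is unknown, and no interval that needs counts was made.

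The 2 kb median was used. Segments were fixed before the data were examined from the bait coordinates: 50 kb below Hoxa5 bait 1, the span from Hoxa5 bait 2 to the Hoxa10 bait, whole and in 3 equal parts, and 30 kb above the Hoxa10 bait. Positions within 5 kb of the labelled bait were left out, and a share is the segment's summed signal as a percent of the sum over the window, which reached 100 kb beyond the baits and so took in all positions. The log2 ratio of 2 shares was the value of each of the 7 comparisons. There was 1 library per group, and no test was made and no p-value is given. A model adding bait, cell type and genotype would leave residual degrees of freedom, but it would assume the same effect of a deletion from every bait and cell type, and would rest on labels that the signal of 4 libraries is at odds with. A range was taken by leaving out each 5 kb block of a segment in turn. The bins named are among the 3 with the largest increase and the 3 with the largest decrease of share in each comparison, a rule also fixed beforehand, over fixed bins of 5 kb. Genes were to be named only where coordinates of the same build placed them. The table of reference genes is of assembly GRCm38, so it gave the order of 13 genes and no positions.

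The plan had foreseen fragment values and windows outside the cluster as a scale of variation. The tables hold running medians over the cluster, so a comparison with outside windows could not be made. The other settings chosen beforehand were leaving out 2 kb or 10 kb around the bait, a window flank of 50 kb, a cap at the 95th percentile, the share of positions above 0, and leaving out the highest position of a segment. A denominator over the whole table is the same as the main one. After the data were examined, 6 alternatives were added: 5 kb left out around all 3 baits, 5 kb left out around each library's own maximum, 5 kb and 10 kb running medians, the 80th percentile of the 2 kb window, and positions at or below 1.5 times the most common nonzero value set to 0. The position of each library's maximum was compared with the labelled bait, and no sample was moved to another group on that ground.

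The share calculation was tested on simulated data made from the 176 positions of the WT library from Hoxa5 bait 1 in MN, with the middle segment changed by known factors and 50 profiles per factor. The largest error of the log2 ratio was 0.15. Noise was drawn independently at each position with a size chosen for the simulation, which sets this error. It checks the calculation and does not show how far real libraries vary. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.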

Results

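Contacts within the mouse HoxA cluster were measured by 4C-seq in embryonic stem cells (ESC) and in motor neurons (MN) derived from them with retinoic acid and a smoothened agonist. 4C-seq ligates and amplifies the DNA found next to a chosen viewpoint, here called the bait, so that the signal along the chromosome shows how often each place was captured with the bait. The Hoxa genes encode homeodomain transcription factors that pattern the head-to-tail axis. CTCF, named in the study's title, is a DNA-binding protein of chromatin boundaries, and the study asked whether it insulates parts of this cluster from each other during neurogenesis. The 3 cell lines were wild type (WT), a line named Δ5|6 and a line named Δ5|6:7|9, the names of the deletions referring to the intervals between Hoxa5 and Hoxa6 and between Hoxa7 and Hoxa9. The 9 libraries were 3 from ESC and 6 from MN, with 1 library per group and no replicates, and no test between groups was made, so every difference below is between single libraries.

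The baits lie on chromosome 6 (mm9) at 52151887 (Hoxa5 bait 1), 52153586 (Hoxa5 bait 2) and 52187161 (called the Hoxa10 bait after the sample titles; another label gives it a name with HOXA7). Baits follow the labelled coordinates. The sample titles do not name them alike in both cell types: HOXA5-A stands for bait 1 in ESC and for bait 2 in MN, where bait 1 is HOXA5-B. In the gene order of the reference annotation, Hoxa1 to Hoxa4 lie on the lower side of Hoxa5, the 3 genes Hoxa6, Hoxa7 and Hoxa9 lie between Hoxa5 and Hoxa10, and Hoxa11 and Hoxa13 lie beyond Hoxa10. The contact signal was summed over an anterior segment (52101887 to 52151887), a middle segment between the Hoxa5 and Hoxa10 baits (52153586 to 52187161, also in 3 equal parts, part 1 next to Hoxa5 and part 3 next to Hoxa10) and a posterior segment (52187161 to 52217161). Each sum is given as a share of the library's signal outside the 5 kb on each side of the labelled bait. The range after a log2 ratio is the lowest and highest value on leaving out each 5 kb block of the segment in turn, and shows spread along the region, not between libraries. No gene coordinates in mm9 were used, so segments and bins are given by position. The sequencing depth is unknown, since the values carry no counts.

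A 4C library should be strongest near its own bait, and 5 of the 9 libraries were strongest on their labelled side, Hoxa5 or Hoxa10. The check by side does not separate the Hoxa5 baits from each other. Both bait 2 libraries had their maximum at 52150984, which is 2602 bp from their own bait and 903 bp from bait 1. The ESC library labelled Hoxa5 bait 1, Δ5|6:7|9 had its maximum there too. The bait 1 libraries in MN had theirs elsewhere, at 52151984 (WT) and 52152984 (Δ5|6:7|9). The library labelled Hoxa5 bait 1, ESC, WT had its maximum at 52186984, beside the Hoxa10 bait, with a mean signal of 0.534 within 5 kb of the Hoxa10 bait against 0.0156 near the Hoxa5 baits. The library labelled Hoxa5 bait 1, ESC, Δ5|6 had its maximum at 52184984, with 0.529 against 0.00571. Both libraries labelled with the Hoxa10 bait in MN had their maximum at 52150984, beside Hoxa5, where the mean signal was 128-fold (WT) and 25.4-fold (Δ5|6) that near the Hoxa10 bait. The labels were kept, and each of these is called the library labelled so. Of the 6 pairs that set a deletion against WT or MN against ESC, 4 were strong at the same side and 2 at opposite sides.

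**Figure D1:**
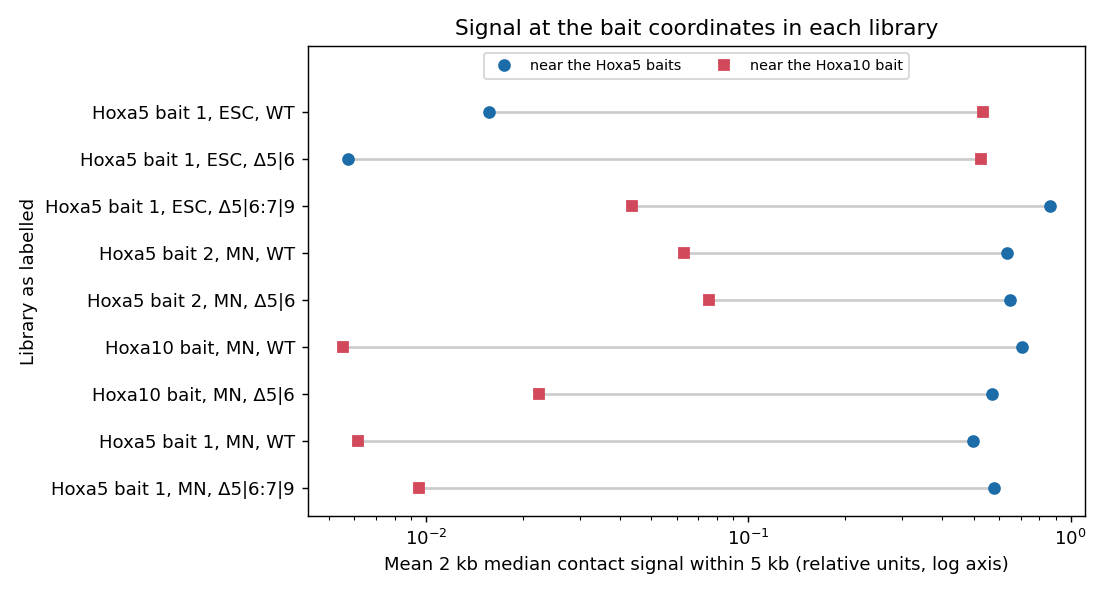
Mean 2 kb median contact signal (relative units, log axis) within 5 kb of the Hoxa5 baits (circles) and of the Hoxa10 bait (squares), with 1 row per library as labelled. In 4 of the 9 libraries the higher signal lies on the side that the label does not name.

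In the pair labelled Hoxa10 bait in MN, the Δ5|6 library had more signal toward the Hoxa10 side of the middle segment than the WT library and less in part 1. Part 2 held 4.75% of the signal in Δ5|6 and 1.03% in WT, a log2 ratio of 2.20 (1.67 to 2.54). Part 3 held 1.51% against 0.356%, a log2 ratio of 2.08 (1.98 to 2.26), and the posterior segment held 1.37% against 0.415%, a log2 ratio of 1.72 (1.26 to 2.02). Part 1 went the other way, with 10.8% against 18.5% and a log2 ratio of -0.78 (-0.83 to -0.78). The comparison set in advance, the anterior share, was 59.7% in Δ5|6 and 60.6% in WT, a log2 ratio of -0.02 (-0.16 to -0.01). The 3 bins of 5 kb with the largest increase of share were 52146887 to 52151886, on the anterior side of Hoxa5 bait 1, with 37.4% against 34.4%, then 52166887 to 52171886, with 2.47% against 0.304%, and 52171887 to 52176886, with 2.29% against 0.496%. The largest decrease lay in 52156887 to 52161886, with 5.72% against 9.98%. Because both libraries were strong beside Hoxa5, the anterior share holds that maximum, and leaving out 5 kb around all 3 baits gave 65.3% against 76.2%, a log2 ratio of -0.22. In the posterior segment only 1 of the 20 positions compared in WT lay above 1.5 times that library's most common nonzero value, so the size of that difference is uncertain. With positions at or below that level set to 0, the posterior log2 ratio was 4.20, with 1.31% against 0.0711%.

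The double deletion was compared with WT in MN from Hoxa5 bait 1, where both libraries were strong at the labelled side. The middle segment held 32.4% of the signal in Δ5|6:7|9 and 25.3% in WT, a log2 ratio of 0.36 (0.18 to 0.75). The excess lay in part 2, with 14.8% against 6.82% and a log2 ratio of 1.12 (0.65 to 1.52). Part 3 held 3.43% against 2.55%, a log2 ratio of 0.42 (0.39 to 0.63), and part 1 held 14.1% against 15.9%, a log2 ratio of -0.17 (-0.98 to -0.11). The bins with the largest increase were 52166887 to 52171886, with 7.43% against 1.83%, and 52171887 to 52176886, with 6.69% against 2.99%. The anterior bins 52116887 to 52121886 (12.9% against 19.8%) and 52121887 to 52126886 (7.74% against 10.8%) had the largest decreases. The posterior segment held 1.35% against 1.67%, and none of its positions in WT lay above 1.5 times that library's most common nonzero value, so no direction is read from it. The ratio of the whole middle segment depended on the processing, from 0.07 with a 10 kb running median to 0.81 with 10 kb left out around the bait.

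**Figure D2:**
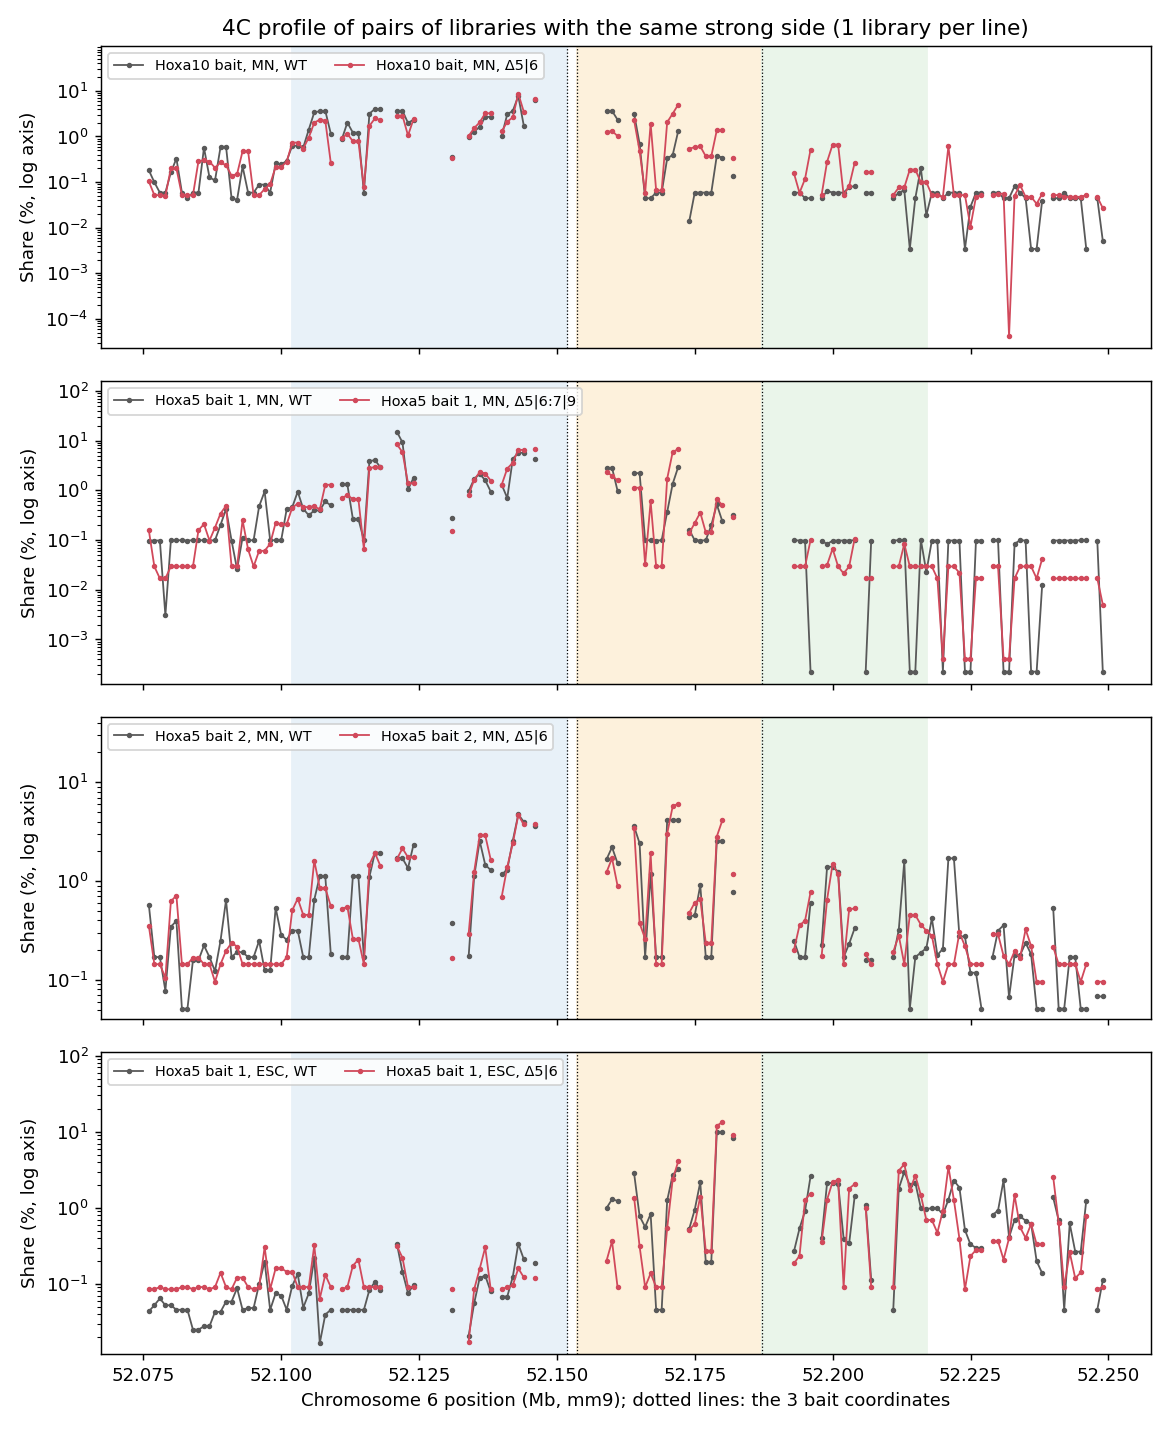
Share of the signal (%, log axis) at each 1 kb position of chromosome 6 (mm9, Mb) for the 4 pairs of libraries that were strong at the same side, WT in grey and deletion in red, with 5 kb around all 3 baits left out of the shares and gaps at positions that are 0 in all libraries. Blue, yellow and green bands mark the anterior, middle and posterior segments, and the bins from 52166887 to 52176886 hold a higher summed share in the deletion library in the upper 2 panels. In the Hoxa5 bait 2 panel, the bin 52171887 to 52176886 is also higher in the deletion library, with 7.80% against 5.97%.

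From Hoxa5 bait 2 in MN, the middle segment held 35.7% in Δ5|6 and 34.6% in WT, a log2 ratio of 0.043 (0.0027 to 0.11), and its sign turned under 6 of the 12 alternatives. Part 1 held 5.96% against 7.55%, a log2 ratio of -0.34 (-0.57 to -0.11). Part 2 held 15.3% against 14.8%, part 3 held 14.4% against 12.3%, and the posterior segment held 12.1% against 10.7%, each with a direction that turned under some alternatives. The largest increase lay in 52186887 to 52191886, with 5.16% against 3.26%, and the largest decrease in 52161887 to 52166886, with 3.36% against 5.19%. Relative to WT, other bins differed more, with 0.80% against 2.29% in 52216887 to 52221886 and 3.02% against 1.37% in 52101887 to 52106886.

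In ESC, the libraries labelled Hoxa5 bait 1 for Δ5|6 and WT were both strong beside the Hoxa10 bait. Part 1, the part of the middle segment far from it, held 0.868% in Δ5|6 and 3.89% in WT, a log2 ratio of -2.17 (-2.90 to -1.24). Part 2 held 3.20% against 4.40%, a log2 ratio of -0.46 (-0.93 to -0.28), and part 3 held 54.7% against 50.4%. The bin 52156887 to 52161886 had the largest decrease, with 0.372% against 2.75%. Lower coverage of the Δ5|6 library was not examined for this pair and stays open. In Δ5|6, 84 positions lay above 1.5 times the library's own most common nonzero value, against 107 in WT. Among the 32 positions compared in the anterior segment these counts were 9 and 18. The whole middle segment, the comparison set in advance, held 58.7% in both, a log2 ratio of 0.0017 (-0.07 to 0.03), and its sign turned under 6 of the 12 alternatives. Most of that share lay in part 3, with the maximum beside the Hoxa10 bait, which leaving out 5 kb around the labelled bait did not remove. Under the record order considered under other observations, this pair would be WT and Δ5|6 in MN, from the Hoxa10 bait.

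**Figure D3:**
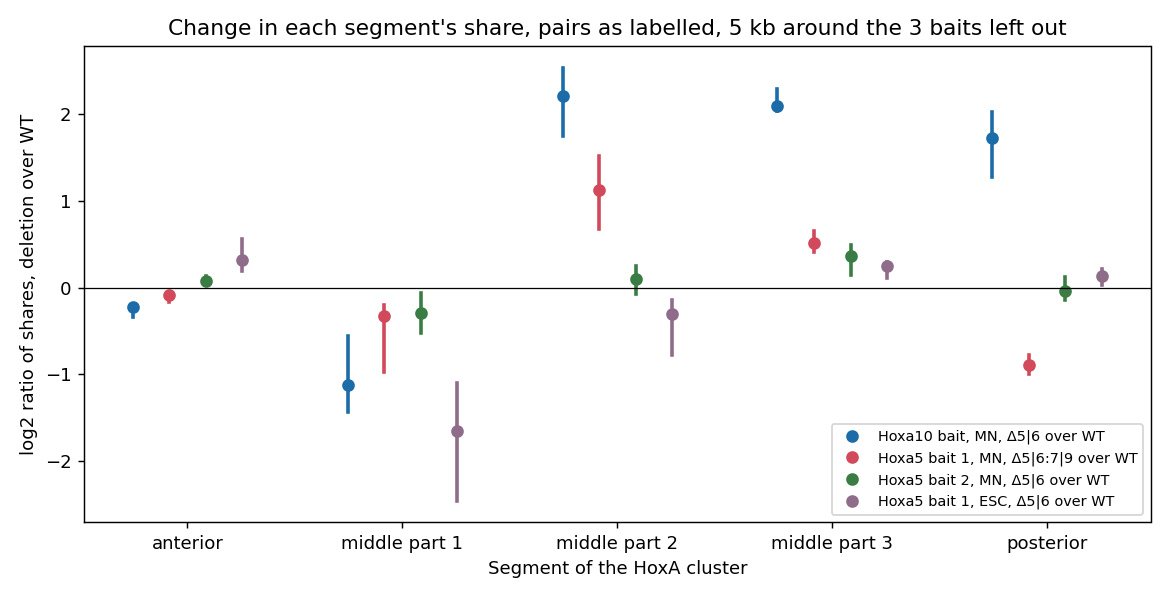
Log2 ratio of each segment's share, deletion over WT (vertical axis), for the segments of the cluster (horizontal axis) in the 4 pairs strong at the same side, with 5 kb around all 3 baits left out. Points are single pairs of libraries as labelled, and lines run from the lowest to the highest value on leaving out a 5 kb block; part 2 was 4.63-fold higher in Δ5|6 for the pair labelled Hoxa10 bait and 2.19-fold higher in Δ5|6:7|9 for Hoxa5 bait 1 in MN.

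The remaining comparisons set libraries with different strong sides against each other, so their values describe these libraries and cannot be read as effects of a deletion or of differentiation. In ESC, the library labelled Hoxa5 bait 1, Δ5|6:7|9 held 52.8% of its signal in the middle segment and 33.9% in the anterior segment, against 58.7% and 1.32% in the library labelled WT. The log2 ratio of the middle share was -0.15 (-0.82 to 0.31). Against the ESC library labelled Δ5|6, the log2 ratio was also -0.15 (-0.85 to 0.39). Between cell types, the WT library from Hoxa5 bait 1 in MN held 25.3% in the middle and 67.3% in the anterior segment, against 58.7% and 1.32% in the library labelled WT in ESC. The log2 ratio of the middle share was -1.22 (-2.12 to -0.75). The double deletion's log2 ratio in MN minus that in ESC was 0.51 (0.06 to 1.57), a difference that rests on the same ESC libraries. Both comparisons across cell types treat bait 1 as the same bait on the ground of the labelled coordinate, while the titles name it HOXA5-A in ESC and HOXA5-B in MN.

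With no replicates, the nearest view of how far libraries differ came from the WT libraries in MN from the Hoxa5 baits, which lie 1699 bp apart and are not replicates. This scale rests on the labels. Under the record order considered under other observations, the library labelled Hoxa5 bait 2, MN, WT would be Δ5|6 in ESC. Both libraries would then be from Hoxa5 bait 1, and the scale would hold a difference of cell type and genotype instead of bait. Bait 2 over bait 1 gave a log2 ratio of 0.46 (0.27 to 1.25) for the middle segment, -1.07 (-1.60 to 0.44) for part 1, 1.11 (0.47 to 1.45) for part 2, 2.27 (2.26 to 2.47) for part 3 and 2.68 (2.47 to 2.86) for the posterior segment. These values depend on the processing: the middle ratio turned to -0.30 with 2 kb left out around the bait, and the part 1 ratio to 0.016 with all 3 baits left out and 0.78 with each library's maximum left out. With the main settings, the double deletion's ratios in MN for the middle segment and part 3 were smaller than these, and its ratio for part 2 (1.12) was of the same size. For the pair labelled Hoxa10 bait, the ratio for part 2 was larger (2.20) with these settings, while those for part 3 and the posterior segment were smaller. This order also depends on the processing. The ratio between the WT libraries was the larger for part 2 under 2 of the 12 alternatives, the 10 kb median (3.25 against 3.19) and the 80th percentile (1.88 against 1.43). The pair's ratio was the larger for part 3 under 4 of the 12, by most with 10 kb left out around the bait (3.06 against 1.99), and for the posterior segment under 1 of 11, the 10 kb median (1.76 against 1.63). The part 1 ratios are not set against this scale, since its sign is not stable. For Δ5|6 from Hoxa5 bait 2 in MN and for the ESC pair labelled Δ5|6, the main ratios for part 2, part 3 and the posterior segment were smaller in size than those between the WT libraries.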

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

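The tests of explanations in this part were chosen after the results were seen, except the test of the flanks of the labelled bait, set before its values were seen, while the comparison of the double deletion between cell types was set in advance. The double deletion's log2 ratio of the middle share from Hoxa5 bait 1 was 0.36 in MN and -0.15 in ESC, a difference of 0.51 that stood out because the single pairs went opposite ways. The difference was not tested, with 1 library per group, and the ESC pair sets libraries with different strong sides against each other.

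In 4 of the 9 libraries the signal was highest on the bait side that the label does not name. Within 5 kb of the labelled baits of these 4 libraries, 0 positions were at 0 or empty beyond those that are so in all 9. This argues against bait-adjacent running medians having been set to 0 or left empty in these libraries alone. Removal of fragments before the medians were taken, or alike in all libraries, would not show in this count. A true contact that outweighs the signal at the labelled bait should still leave a local rise at that bait. The mean within 5 kb of that bait was 0.13 to 0.93 of the mean of its higher flank at 5 to 10 kb. In the other 5 libraries this ratio was 1.70 to 3.54. On leaving out single positions, its highest value was 0.144 in the ESC library labelled WT. It was 0.771 in the library labelled Hoxa10 bait, MN, WT. No local rise was thus seen in these 2 libraries, a reading by library made after the values were seen. In the other 2 of the 4 the ratio reached 1.15 and 1.02. Both lie below 1.39, the lowest value on leaving out single positions in the other 5 libraries. The rule set beforehand counted against a true contact only if the ratio stayed below 1 in all 4 libraries on leaving out any position. It was not met, so the test does not decide, and a true contact stays open. The 4 maxima lay within 2177 bp of another bait coordinate of the series, which restates the pattern and gives no separate support for a mislabelled sample or a table attached to another record. That explanation stays open for all 4 libraries.

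In the pair labelled Hoxa10 bait in MN, the mean signal of middle parts 2 and 3 relative to the anterior segment was 5.29-fold higher in Δ5|6 than in WT, with 5 kb around all 3 baits left out (4.10-fold to 6.28-fold on leaving out single blocks). With WT raised to 1.5 times its most common nonzero value, the log2 ratio was 2.29, so WT values below that level do not account for it. The most common value is not a lowest level. A detection floor that differs between the libraries is therefore argued against only up to the level tried. Lower coverage of the WT library cannot be told apart from an effect of the deletion: outside these parts 22 more positions lay above 1.5 times the library's own such value in Δ5|6 (71 against 49 of 111), though at the 7 positions within them above it in both libraries the log2 ratio was 2.16. A mislabelled sample cannot be told apart from an effect of the deletion, because no value in the tables shows the genotype. Away from the labelled bait, 2 of the 2 libraries peaked at the same position, 52150984. That mismatch is shared and does not bear on the difference between them. Under the record order considered under other observations, they would still be WT and Δ5|6 in MN, from a Hoxa5 bait. The deletion may also act on this contact, which stays an untested hypothesis without replicates.

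In the pair from Hoxa5 bait 1 in MN, the same quantity was 2.19-fold higher in Δ5|6:7|9 (1.57-fold to 2.77-fold). With WT raised in the same way the log2 ratio was 1.08, so a differing detection floor is again argued against only up to the level tried. Lower coverage of the WT library cannot be told apart here either, with 15 more positions above the level in Δ5|6:7|9 outside these parts (55 against 40 of 111) and a log2 ratio of 1.13 at the 9 positions within them above it in both libraries. A mislabelled sample cannot be told apart from the deletion's effect by the bait alone: 0 of the 2 libraries peaked away from the labelled side, but no value in the tables shows the genotype. Variation between libraries stays open as well, since the libraries labelled WT from the Hoxa5 baits in MN differed by as much in part 2, a scale that rests on those labels.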

How the results depend on the processing

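Of the 12 alternatives, the 6 that change the bait mask by library, the running window, the percentile or the low values were chosen after seeing the data. A denominator over the whole table equals the main one and gave no value of its own. The cause of each change below was not tested, except where the masks of the Hoxa5 baits differ, as given below. The share of positions above 0 gave 0 in every comparison from the same bait because the same positions are 0 in all libraries. The higher part 2 share kept its direction under the other 11 alternatives for the pair labelled Hoxa10 bait (1.43 to 4.03) and for the double deletion from Hoxa5 bait 1 in MN (0.55 to 2.39). The lower part 1 share of the ESC pair did so as well (-2.89 to -1.25). Depth could not be examined, since no counts are given.

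For Δ5|6 from Hoxa5 bait 2 in MN, the log2 ratio of the middle share (0.043) turned to -0.039 with 2 kb left out, -0.028 with the cap, -0.041 without the highest position, -0.16 and -0.20 with 5 kb and 10 kb running medians and -0.096 with the 80th percentile. Its part 2 turned in the same order to -0.0079, -0.16, -0.40, -0.0053, -0.20 and -0.21. Part 3 turned to -0.022 and -0.10 with the 5 kb and 10 kb medians, and the posterior segment to -0.044 with all 3 baits left out. For the double deletion from Hoxa5 bait 1 in MN, the middle ratio (0.36) was 0.14 with 2 kb and 0.81 with 10 kb left out, 0.10 with the cap, 0.13 with each maximum left out, 0.098 and 0.066 with the 5 kb and 10 kb medians and 0.15 with the 80th percentile. Its posterior ratio turned to 0.20 with the 80th percentile. For the pair labelled Hoxa10 bait, the anterior ratio (-0.02) was -0.0054 with 10 kb left out, -0.22 with all 3 baits left out, -0.23 with each maximum left out, -3.94e-05 with the 5 kb median and -0.22 with the 80th percentile, and turned to 0.0099 with the 10 kb median.

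For the ESC pair labelled Δ5|6 and WT, the middle ratio (0.0017) turned to -0.11 with the cap, -0.076 without the highest position, -0.022 with all 3 baits left out, -0.72 with each maximum left out, -0.051 with the 10 kb median and -0.17 with the 80th percentile. Its part 3 turned to -0.64 with each maximum left out and -0.082 with the 80th percentile, and its posterior ratio to -0.0061 with the 80th percentile. The part 2 ratio of this pair (-0.46) kept its direction under 11 of the 12 alternatives and was -1.19 at its lowest. For the ESC pair labelled Δ5|6:7|9 and WT, the middle ratio (-0.15) was -0.84 with the 5 kb median and turned to 0.27 both with each maximum left out and with the 80th percentile. The WT ratio of MN over ESC (-1.22) was -0.63 with 2 kb left out. The double deletion's ratio in MN minus ESC (0.51) turned to -0.15 with each maximum left out and -0.12 with the 80th percentile. In ESC, the double deletion over Δ5|6 (-0.15) turned to 0.99 with each maximum left out and 0.44 with the 80th percentile.

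Between the WT libraries in MN from the Hoxa5 baits, bait 2 over bait 1, the middle ratio (0.46) was 0.17 with the cap and turned to -0.30 with 2 kb left out and to -0.11 with the share of positions above 0. The part 1 ratio (-1.07) turned to 0.31 with 10 kb left out, 0.016 with all 3 baits left out and 0.78 with each maximum left out. The main masks of these libraries leave out different positions of part 1, and leaving out all 3 baits makes the masks alike.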

Other observations

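The 3 parts of the middle segment were fixed in advance, while reading part 1 across pairs and the tests of record order were chosen after the results were seen. Part 1 of the middle segment, the part next to Hoxa5, had a lower share in the deletion library than in WT in 4 of the 4 pairs strong at the same side, whichever side that was. The log2 ratios were -0.34 for Hoxa5 bait 2 in MN, -0.17 for the double deletion from Hoxa5 bait 1 in MN, -0.78 for the pair labelled Hoxa10 bait and -2.17 for the ESC pair. In each pair the direction held under 11 of the 12 alternatives, and the remaining one, the share of positions above 0, gave 0. The size depended on the processing: over the 11 it ran from -0.61 to -0.015 for Hoxa5 bait 2, from -1.02 to -0.034 for the double deletion, from -1.13 to -0.22 for the pair labelled Hoxa10 bait and from -2.89 to -1.25 for the ESC pair. Part 1 rests on 4 positions once the surroundings of all baits are left out, and for the double deletion 1 of the 4 was higher in the deletion library. The WT libraries in MN from the Hoxa5 baits had a main log2 ratio of -1.07 in part 1, whose sign was not stable. Their main masks leave out different positions of part 1, and with all 3 baits left out the ratio was 0.016. The count of pairs rests on the labels: under the record order considered next, the Hoxa5 bait 2 pair would be Δ5|6 and Δ5|6:7|9 in ESC, without a WT library. The pair labelled ESC would then be WT and Δ5|6 in MN, from the Hoxa10 bait.

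The libraries with their maximum beside the Hoxa10 bait were the first 2 in record order, while the titles name that bait for the sixth and seventh records. A hypothesis is that tables were attached to records in the alphabetical order of bait and cell type, where HOXA10 comes before HOXA5. Under it, 9 of the 9 libraries would be strong at the side their record names, against 5 as labelled, among 36 ways to place 2 libraries. That order was thought of on seeing these maxima, so the count is no independent evidence. A further expectation, that the 3 libraries which would then be ESC from the same bait resemble each other most, was not met, and 2 of the 3 correlated best with a library outside the 3. Their lowest correlation across 127 positions, which are not independent replicates, was 0.827, and their highest with the other 4 libraries strong beside Hoxa5 was 0.870, a difference of -0.0432 (-0.055 to -0.034 on leaving out single 5 kb blocks). Of the 12 correlations with those 4 libraries, 9 were below the lowest within the 3, and the mean was 0.835 within the 3 and 0.775 with the others. That weaker form was not predicted and is read from the same correlations, so it is no separate support. As labelled, 2 of the 3 also share bait and cell type, so likeness between those 2 does not set the hypothesis apart from the labels. The correlations above that lowest value, 0.851, 0.868 and 0.870, were each with a library labelled as a deletion in MN. Across the deletion libraries in MN the correlations ran from 0.756 to 0.870, and across the WT libraries in MN from 0.668 to 0.792. The expectation took no account of genotype, so its failure does not decide the question. With 5 kb around all 3 baits left out, part 3 held 5.72% to 9.24% of the signal in the 3 libraries. In the other 4 it held 1.04% to 4.42%. The posterior segment held 5.88% to 9.22% in the 3 and 0.796% to 4.01% in the 4. The anterior segment held 43.1% to 45.7% in the 3 and 65.3% to 76.2% in the 4. The whole middle segment held 33.6% to 37.7% in the 3 and 16.8% to 25.6% in the 4. The ranges of middle parts 1 and 2 overlapped. The hypothesis would make the 3 libraries ESC and the 4 MN, so these shares would then set the cell types apart, which was not tested. The hypothesis stays open, and no other comparison of genotypes or cell types was made under it.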
